A study of Mus musculus with 12 samples.

How the data were processed

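Brains were kept in RNAlater, total RNA was extracted with Trizol and libraries were made with a NEBNext Ultra RNA kit, per the labels' protocols. Per the labels, the authors used Trimmomatic, FastQC, STAR and HTSeq on build mm10 to make the read count of each gene. Their versions, and the annotation, are not given in the sources used here. The deposited count table holds whole counts for 21983 genes in 12 libraries, with no further scaling. The authors' deposited tables of 3 comparisons also give a log2 fold change, an unadjusted and an adjusted p-value, a normalized signal (the read count divided by 1 factor per library) and an FPKM for each gene, per the file headers. The tool behind the deposited log2 fold change and p-value, and the gene lengths behind the deposited FPKM, are not given in the sources used here. The signal and FPKM values were not used for tests.

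In 2212 genes of the count table, those with names of 8 or more characters, values were displaced by the long name and were put back in their columns. For these genes, the values of treated library 4 differed from the read counts in the authors' deposited tables in 98 of 107 genes present in both, while 0 values differed in the other libraries. In the genes with shorter names that these tables hold (604, 1274 and 1381), 0 values differed. The displaced genes were therefore fitted with 11 libraries and all others with 12. This departs from the planned fit of all 12 libraries and was decided after the files were seen. 70 names were unusable, 26 of them turned into dates. Coordinates were taken from GENCODE M21 by symbol, which matched 21871 genes (99.5%). Genes with near-identical copies, such as Hba-a1, Hbb-bs, Hspa1a and the H2 genes, can share reads, and the kit named in the labels is not described there as strand-specific, so antisense reads were not separated.

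Counts were scaled by TMM, filtered with filterByExpr and tested in 1 edgeR quasi-likelihood model with a mean per group and 3 contrasts (edgeR 4.0.16, R 4.3.3). P-values were adjusted by Benjamini-Hochberg over 14624 genes within each comparison, and a gene was called at an adjusted p below 0.05. The median log2 fold change over all genes was within 0.05 of 0 in each comparison, so the scaling was left unchanged. Gene lists were tested with camera on log2 CPM (limma 3.58.1, preset correlation 0.01), again with the correlation estimated from the data, and with fry. Set tests and list scores left out the displaced genes. They used 27 of 28 tested interferon-stimulated, 24 of 25 reactive astrocyte and 11 of 12 complement genes. For endothelial activation it was 18 of 19, and for heat shock and unfolded protein response 15 of 16. Adjusted p-values of lists are Benjamini-Hochberg values over 35 lists. With an estimated correlation they are often far larger. Where a list passed and no such value is given, its call held with one (adjusted p 0.00118 to 0.0476). The fry test, which asks whether genes of a list move one way, passed 27, 24 and 22 lists in ECM against control, treated ECM against ECM and treated ECM against control. Other tools were DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

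The comparisons, 37 gene lists, a panel of 38 genes, the share remaining after treatment and the alternatives were fixed before the data were examined. Genes named are the panel, up to 4 members per list, the 10 called genes per direction and comparison with the largest fold, a mean of at least 1 CPM in the higher group and no overlap between libraries of the groups, and by the same rule genes called in all 3 comparisons or in both with treated ECM alone. Some genes of this rule are not reported here. Predicted gene models were left out, and preference among list members for calls kept in all 12 omissions of 1 library was decided after the results were seen. The share remaining is the treated against control log2 fold change divided by that of ECM against control, over genes called in ECM with at least a 2-fold change. The sex-linked list had 0 of 5 members in the test and was not analysed here. For a gene with 0 counts in a group, fold changes are bounds against 3 counts over that group. With 1 to 3 counts they are ratios with 95% intervals, which cover counting error only.

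On counts simulated from the real means and library sizes (14271 genes), edgeR recovered 34 of 100 genes changed by log2 1 and 97 of 100 changed by log2 2 in ECM against control, with 6 unchanged genes called. In treated ECM against ECM it recovered 0 of 100 at log2 0.5 and 9 of 100 at log2 1, and in treated ECM against control 0 and 23 of 100. A true share of 0.5 was estimated as 0.491. Means and spread were those of the controls, and few genes were changed. The recovery rates therefore need not hold for the real fit.

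Libraries differed from each other by more than sampling noise, with none duplicated. Chosen after the files were seen were the 11-library fit, the covariate, GC-content and displaced-gene alternatives, the omission of 3 libraries that stand apart, the omission of control 4 and ECM 4, and the exchange of these 2 libraries. A list of further cerebellar genes first shared 4 genes with the fixed list, which were removed before its result was viewed. The label of the platelet test was changed after its value was seen and then put back, as given beside that test. The range of the cerebellum score over controls was read as undecided once the range without control 4 was seen, and before that as evidence against infection or treatment. The figures and their genes were also chosen after the results were seen. Alignment and raw reads were not analysed here.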

Results

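Gene expression was measured by RNA-seq in brains of 6-week-old C57BL/6 mice in 3 groups: control mice, mice with experimental cerebral malaria (ECM), and ECM mice treated with artesunate for 4 days. Each group had 4 libraries, numbered 1 to 4. The groups are separate libraries, so words such as rose, fell and kept compare group means and not change within an animal. Time since infection was not part of any comparison and was not separated from treatment. Reads assigned to genes per library were 18337509, 15553485, 13422447 and 15826838 in controls, 13342177, 13736393, 13999627 and 18886822 in ECM, and 18381410, 14250893, 15384870 and 15096568 in treated ECM. The labels give 4 replicates per group and do not state that each library is a separate animal, so every p-value measures the spread between samples. Of the genes, 14624 were tested in each comparison. Levels are CPM (read counts scaled to library size), mean ± SD over the 4 libraries of a group, and log2 fold changes are given ± standard error. For Serpina3f, Serpina3n and Tnfrsf25 the treated values come from 3 libraries, without treated 4.

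ECM against control asks which brain transcripts differ in mice with cerebral malaria. Transcripts of interferon responses, antigen presentation, chemokines, cytotoxic lymphocytes and monocytes rose, many of them from near absence. Reactive astrocyte, activated microglia, complement and endothelial activation genes rose with them. Gpr17, Slco1c1 and Drd2 were among the genes that fell, and hemoglobin transcripts nearly disappeared. Striatum markers were called lower, a call lost with an estimated correlation.

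**Figure D1:**
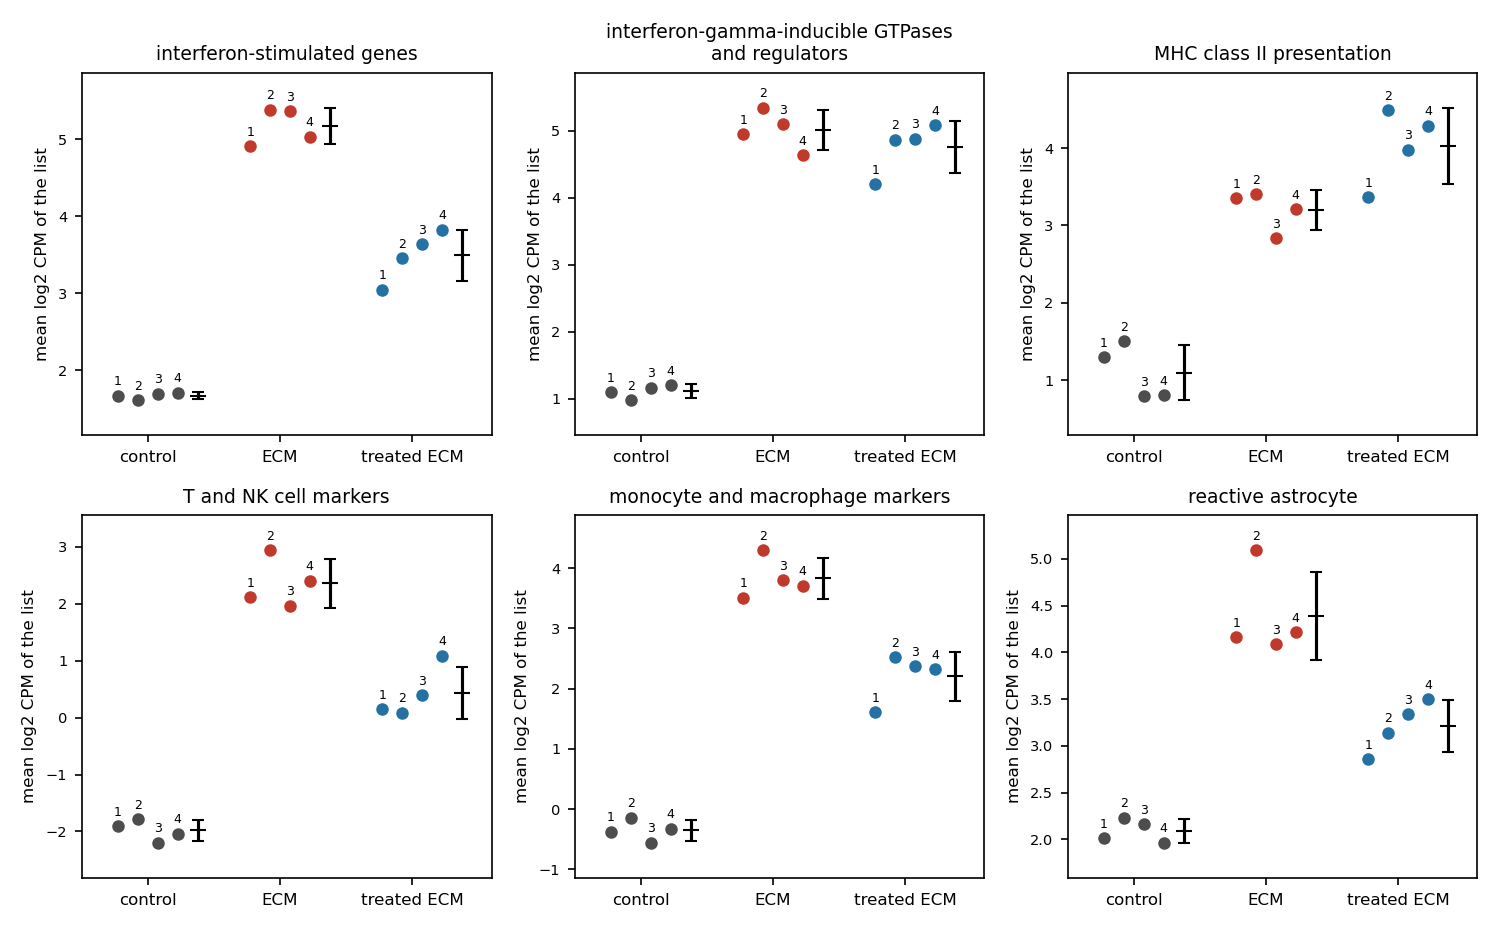
Scores of gene lists per library in control, ECM and artesunate-treated ECM, as mean log2 CPM of the tested members without displaced genes. Points are libraries numbered by replicate and the black bar is the mean ± SD over 4.

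Interferon-stimulated genes were higher in ECM in 28 of 28 (28 adjusted over the list alone), with a median log2 fold change of 3.89 (set test, adjusted p = 1.14e-47, and adjusted p = 0.00867 with an estimated correlation). Rsad2, which encodes the antiviral enzyme viperin (build mm10, chromosome 12, 26442746 to 26456452), rose from 1.36 ± 0.432 to 56.7 ± 17.4 CPM (log2 fold change 5.38 ± 0.31, adjusted p = 2.26e-07). Ifit1, which binds foreign RNA ends, rose from 5.74 ± 1.78 to 125 ± 58.6 CPM, the ubiquitin-like modifier Isg15 from 1.24 ± 0.339 to 38.5 ± 13.7 CPM, and Mx1, an antiviral dynamin-like GTPase, from 0.376 ± 0.113 to 12.8 ± 4.43 CPM. Interferon-gamma-inducible GTPases and regulators were higher in 17 of 19 (18 adjusted over the list alone), with a median of 4.36 (adjusted p = 6.28e-36, and adjusted p = 0.00867 with an estimated correlation). Among them Gbp2, which coats pathogen vacuoles (chromosome 3, 142620602 to 142638008), rose from 4.89 ± 0.588 to 259 ± 106 CPM (log2 fold change 5.73 ± 0.35, adjusted p = 3.42e-07), the immunity-related GTPase Iigp1 from 2.71 ± 0.591 to 184 ± 65.0 CPM, and the transcription factor Irf1 from 4.11 ± 0.8002 to 32.9 ± 1.67 CPM. The tryptophan-degrading enzyme gene Ido1 did not pass the test (log2 0.33 ± 0.35, adjusted p = 0.653).

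Antigen presentation rose in both classes. MHC class I genes were higher in 19 of 19 (19 adjusted over the list alone) with a median of 2.82 (adjusted p = 1.28e-30). The peptide transporter gene Tap1 rose from 2.68 ± 0.403 to 68.8 ± 14.2 CPM (log2 fold change 4.67 ± 0.23, adjusted p = 8.85e-08), and the light chain gene B2m from 129 ± 52.6 to 909.6 ± 482 CPM. MHC class II genes were higher in 5 of 7 (6 adjusted over the list alone) with a median of 2.14 (adjusted p = 6.21e-08). The invariant chain gene Cd74 rose from 4.31 ± 1.63 to 52.3 ± 12.1 CPM and H2-Aa from 1.46 ± 0.561 to 12.8 ± 3.99 CPM, while their transactivator Ciita did not pass the test (1.16 ± 0.121 and 1.38 ± 0.649 CPM, adjusted p = 0.734). The T-cell inhibitory ligand gene Cd274 rose 39.7-fold (adjusted p = 8.85e-08).

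Chemokine genes were higher in 13 of 15 (13 higher and 1 lower adjusted over the list alone) and lower in 1 (median 4.72, adjusted p = 6.97e-15). The T-cell attractant Cxcl10 (chromosome 5, 92346638 to 92348889) rose from 0.405 ± 0.322 to 118 ± 79.1 CPM (log2 fold change 8.22 ± 0.67, adjusted p = 3.72e-06), and Cxcl9 from 0.101 ± 0.0962 to 24.5 ± 10.6 CPM. The monocyte attractant Ccl2 rose from 0.0965 ± 0.113 to 12.8 ± 4.59 CPM, and Ccl5 from 0.0767 ± 0.0683 to 25.1 ± 15.8 CPM. Cxcl12, a homeostatic chemokine of stroma and endothelium, fell from 57.2 ± 10.03 to 23.6 ± 2.42 CPM (adjusted p = 0.000586). Cytokine genes were higher in 10 of 13 (10 higher and 1 lower adjusted over the list alone, median 1.65, unchanged with 3 members at their bound, adjusted p = 2.26e-10). Ifng, the interferon of activated lymphocytes, had 0 counts in controls and was at least 54.7-fold higher in ECM, and Tnf at least 31.2-fold. Il1b rose from 0.103 ± 0.0842 to 1.63 ± 0.550 CPM, and Il6 had too few counts to be tested.

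T and NK cell markers were higher in 18 of 19 (18 adjusted over the list alone), with a median of 6.30, or 5.76 with the 3 members that had a group at 0 placed at their bound (adjusted p = 4.56e-27). Gzmb, a cytotoxic granule protease, had 2 counts over the controls and 4003 over ECM libraries, a ratio of 2175-fold (counting interval 602 to 17967). Gzma rose from 0.0593 ± 0.0786 to 27.0 ± 14.6 CPM and Cd8a from 0.0676 ± 0.0918 to 10.5 ± 2.46 CPM, and the pore-forming Prf1 had 2 and 187 counts, a ratio of 102-fold (counting interval 27.7 to 845). Cd4 did not pass (log2 -0.59 ± 0.35, adjusted p = 0.366). Monocyte and macrophage markers were higher in 12 of 15 (12 adjusted over the list alone, median 4.51, adjusted p = 3.26e-23). Ly6c2 of inflammatory monocytes had 2 and 1604 counts, a ratio of 872-fold (counting interval 241 to 7203), and the Fc receptor gene Fcgr4 rose from 0.158 ± 0.133 to 24.5 ± 8.38 CPM. Neutrophil markers were higher in 4 of 6 (4 adjusted over the list alone, median 3.91, adjusted p = 3.15e-06), with S100a8 rising from 0.107 ± 0.1001 to 1.79 ± 0.565 CPM and its partner S100a9 from 0.0819 ± 0.0652 to 1.22 ± 0.889 CPM. Of B cell markers only 2 were tested and 0 passed in any comparison.

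Innate sensing and NF-kB genes were higher in 18 of 21 (19 adjusted over the list alone, median 1.65, adjusted p = 7.78e-18). The RNA sensor Tlr7 rose from 5.86 ± 3.34 to 23.5 ± 5.11 CPM and Tlr13 from 4.62 ± 1.54 to 17.7 ± 3.94 CPM. Inflammasome and cell death genes were higher in 11 of 17 (13 adjusted over the list alone, median 1.46, adjusted p = 4.07e-10). The necroptosis effector Mlkl rose from 0.254 ± 0.145 to 5.26 ± 1.49 CPM and the nucleic acid sensor Zbp1 from 0.281 ± 0.188 to 21.996 ± 5.89 CPM. Complement genes were higher in 11 of 12 (11 adjusted over the list alone, median 2.12, adjusted p = 1.37e-11), with C4b rising from 15.7 ± 4.30 to 207 ± 80.04 CPM and C1qb from 35.8 ± 3.49 to 137 ± 32.0 CPM.

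Activated microglia genes were higher in 12 of 16 (12 adjusted over the list alone, median 1.76, adjusted p = 1.59e-12), among them the costimulatory Cd86 (2.68 ± 0.568 to 11.6 ± 3.65 CPM). Homeostatic microglia genes fell in 4 of 12 (5 lower and 1 higher adjusted over the list alone, median -0.37, adjusted p = 0.0120). That call was lost with an estimated correlation (adjusted p = 0.222) and without ECM 3 (adjusted p = 0.0755). Gpr34, a lysophospholipid receptor of microglia, fell from 16.5 ± 3.64 to 4.11 ± 2.09 CPM, while P2ry12 (adjusted p = 0.0509) and Tmem119 (adjusted p = 0.982) did not pass. Reactive astrocyte genes were higher in 21 of 25 (22 adjusted over the list alone, median 2.08, adjusted p = 7.36e-19). Gfap, the astrocyte intermediate filament, rose from 226 ± 45.7 to 957 ± 127 CPM (log2 fold change 2.08 ± 0.24, adjusted p = 5.20e-05), the protease inhibitor Serpina3n from 17.8 ± 1.34 to 142 ± 29.7 CPM, and the iron-siderophore carrier Lcn2 from 0.396 ± 0.171 to 50.8 ± 32.3 CPM. Homeostatic astrocyte genes were higher in 2 of 12 (2 adjusted over the list alone, median 0.13, adjusted p = 0.446).

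Endothelial activation, adhesion and coagulation genes were higher in 14 of 19 (16 adjusted over the list alone, median 1.66, adjusted p = 7.81e-15). The leukocyte ligand Icam1 rose from 1.99 ± 0.430 to 32.7 ± 11.5 CPM (log2 fold change 4.03 ± 0.29, adjusted p = 1.09e-06), and the platelet and endothelial selectin Selp from 0.179 ± 0.187 to 3.84 ± 1.01 CPM. Vcam1 was higher (32.6 ± 5.60 to 55.1 ± 15.0 CPM, adjusted p = 0.0217), with the call lost in 3 of 12 omissions of 1 library, without control 1 to 3 (adjusted p up to 0.0782). Of the endothelial identity and tight junction genes 5 of 17 (6 higher and 3 lower adjusted over the list alone) rose and 3 fell (median 0.11, adjusted p = 0.362). The junctional cadherin Cdh5 rose from 16.0 ± 2.50 to 54.0 ± 10.3 CPM and Pecam1 from 32.1 ± 10.02 to 89.6 ± 18.6 CPM. Slco1c1, the thyroid hormone and organic anion carrier of brain endothelium (chromosome 6, 141524368 to 141570177), fell from 55.8 ± 5.08 to 20.3 ± 1.74 CPM (log2 fold change -1.45 ± 0.15, adjusted p = 2.22e-05), and outside the list the organic anion carrier Slc22a8 from 17.5 ± 2.19 to 3.53 ± 0.474 CPM. Cldn5 rose (log2 1.69 ± 0.41, adjusted p = 0.0174), a call lost without control 3 or ECM 4 (adjusted p up to 0.0517), and Ocln did not pass (adjusted p = 0.575). Pericyte and mural genes were higher in 2 of 11 (2 adjusted over the list alone, median 0.17, adjusted p = 0.152).

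Myelinating oligodendrocyte genes were lower in 2 of 15 (6 lower and 1 higher adjusted over the list alone) and higher in 1 (median -0.50, adjusted p = 0.124, or 0.0214 without control 4). Ugt8a, which makes myelin galactolipids, fell from 118 ± 24.4 to 35.1 ± 6.17 CPM (log2 fold change -1.75 ± 0.19, adjusted p = 3.70e-05), while Mbp (adjusted p = 0.959) did not pass. Oligodendrocyte precursor genes were lower in 2 of 10 (2 adjusted over the list alone, median -0.27, adjusted p = 0.140), with Gpr17 of committed precursors falling from 48.7 ± 7.99 to 12.03 ± 6.38 CPM (adjusted p = 0.00288). Striatum markers were lower in 5 of 9 (6 adjusted over the list alone, median -0.89, adjusted p = 1.24e-05, and adjusted p = 0.164 with an estimated correlation). The dopamine receptor gene Drd2 fell from 36.9 ± 6.90 to 12.8 ± 3.26 CPM and the phosphodiesterase gene Pde10a from 285 ± 68.4 to 122 ± 17.6 CPM. Choroid plexus markers were lower in 3 of 12 (3 adjusted over the list alone, median -1.02, adjusted p = 0.000566, and adjusted p = 0.237 with an estimated correlation). Transthyretin, Ttr, spread widely and did not pass (343 ± 276 and 94.7 ± 181 CPM, adjusted p = 0.485), and without ECM 4 it did (log2 -6.37, adjusted p = 0.00421). Without control 4, ECM 2 and ECM 3, 5 myelinating, 1 precursor, 8 striatum and 0 choroid plexus genes were called lower (choroid plexus median -0.78), and 1, 1, 0 and 0 higher. Neuron markers did not pass (0 of 22, 0 adjusted over the list alone, median -0.10, adjusted p = 0.425). With the cerebellum score in the model 1 was called higher and 1 lower, and the same counts were found without these 3 libraries.

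Heme, iron and oxidative stress genes were higher in 10 of 19 (11 higher and 2 lower adjusted over the list alone) and lower in 2 (median 0.74, adjusted p = 1.77e-07). Hmox1, the inducible heme oxygenase, rose from 4.10 ± 0.698 to 68.2 ± 19.9 CPM (log2 fold change 4.05 ± 0.28, adjusted p = 9.20e-07), the oxidase subunit gene Cybb from 0.848 ± 0.0887 to 25.3 ± 5.31 CPM, the metal-binding Mt1 from 346 ± 39.3 to 1323 ± 779 CPM, and the iron exporter Slc40a1 fell from 11.3 ± 1.01 to 5.19 ± 1.16 CPM. Erythroid transcripts were lower in 3 of 4 (4 adjusted over the list alone, median -6.63, or -5.43 with 1 at its bound, adjusted p = 4.21e-06). Hbb-bs fell from 19.5 ± 10.04 to 0.126 ± 0.0995 CPM (log2 fold change -7.19 ± 0.80, adjusted p = 4.73e-05) and Hba-a1 from 7.69 ± 3.24 to 0.0997 ± 0.0758 CPM; their near-identical copies share reads. Immediate early genes were higher in 9 of 17 (12 adjusted over the list alone, median 1.36, adjusted p = 2.76e-07, and adjusted p = 0.164 with an estimated correlation), with Fos rising from 11.96 ± 7.60 to 74.7 ± 57.0 CPM and Cyr61 from 4.76 ± 1.16 to 71.3 ± 13.2 CPM.

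The largest rises in ECM were in genes with few or no control counts. Chil3, a chitinase-like protein of macrophages, rose 3964-fold (counting interval 711 to 156630.0, adjusted p = 3.42e-07). With 0 control counts, the protease inhibitor gene Serpina3f rose at least 352-fold (adjusted p = 8.91e-06) and the lectin receptor gene Clec4e at least 184-fold (adjusted p = 0.000128). From the same base rose the CD8 chain gene Cd8b1 at least 174-fold (adjusted p = 0.000422) and the ubiquitin-like Ubd at least 169-fold (adjusted p = 0.000115). Also with 0 control counts, the DNA sensor gene Ifi205 rose at least 117-fold (adjusted p = 0.000507), the lymphocyte GTPase gene Gimap3 at least 84.0-fold (adjusted p = 0.000156) and the interleukin-1 antagonist gene Il1rn at least 79.7-fold (adjusted p = 4.82e-05). Among the largest falls, Hbb-bt with 0 ECM counts was lower by at least 27.6-fold (adjusted p = 0.0119). Gkn3, an arterial endothelial gene, fell from 4.38 ± 1.23 to 0.142 ± 0.139 CPM (adjusted p = 0.000109), the collagen gene Col14a1 from 1.75 ± 0.635 to 0.345 ± 0.298 CPM (adjusted p = 0.00604) and the endothelin gene Edn3 from 8.93 ± 0.598 to 1.98 ± 0.763 CPM (adjusted p = 0.000124). The BMP antagonist gene Sostdc1 fell from 2.92 ± 0.811 to 0.625 ± 0.562 CPM (adjusted p = 0.0164), Fam180a from 2.30 ± 0.576 to 0.459 ± 0.135 CPM (adjusted p = 0.000300) and the zinc finger gene Zfp493 from 5.14 ± 2.15 to 1.198 ± 0.490 CPM (adjusted p = 0.00120).

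Library composition varied inside groups. Across genes, the deviation of a library from the mean of all libraries followed GC content to differing degrees. The rank correlation ran from -0.675 in control 4 and -0.488 in ECM 3 to 0.547 in ECM 4. It was 0.415 to 0.529 in the treated libraries. The second principal component of log2 CPM held 29.9% of the variance, and its loadings correlated with GC content at 0.715. The cerebellum score was low in control 4, ECM 1 and ECM 3 (1.02, 1.45 and 0.83 log2 CPM), cerebellum markers did not pass (0 of 11, 0 adjusted over the list alone, median -0.45, adjusted p = 0.113), and the list was called lower without control 4 (adjusted p = 0.00178), ECM 2 (0.00382) or ECM 4 (0.0472). Mitochondrial reads made up 15.8% of ECM 2, 13.7% of ECM 3 and 11.1% of control 4 against 4.95% in the lowest library. Mitochondrially encoded mRNAs were higher in 1 of 12 (1 adjusted over the list alone, median 0.74, adjusted p = 0.00431), a call lost with an estimated correlation (adjusted p = 0.454) and without ECM 2 (adjusted p = 0.0783). Oligodendrocyte, striatum and choroid plexus genes also differ between brain regions, and were measured in libraries whose composition differed.

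**Figure D2:**
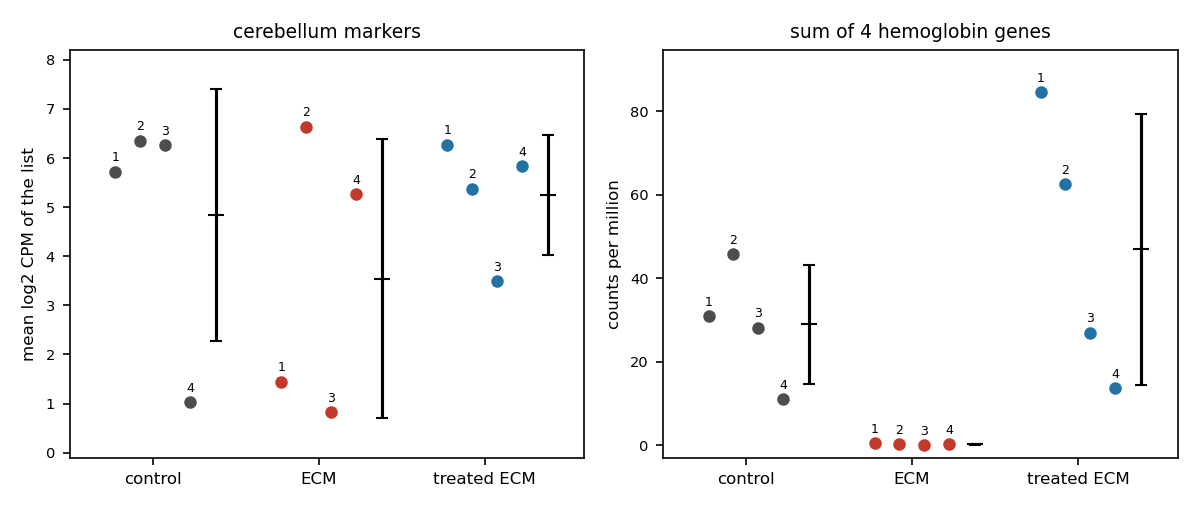
Cerebellum score (mean log2 CPM) and summed CPM of 4 hemoglobin genes in control, ECM and artesunate-treated ECM. Points are libraries numbered by replicate and the black bar is the mean ± SD over 4.

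Of 14624 genes, 1501 passed at an adjusted p below 0.05 in ECM against control (edgeR quasi-likelihood, Benjamini-Hochberg), 1040 higher and 461 lower. With a change of at least 2-fold, 829 were higher and 157 lower. At an adjusted p below 0.05, 718 were higher and 148 lower in the 8 control and ECM libraries alone. They were 1627 and 1243 with the cerebellum score, and 1556 and 1166 without control 4, ECM 2 and ECM 3. The 3 groups share 1 estimate of spread. Squared differences between libraries were 9.07 to 24.4 times sampling noise in treated pairs, 13.7 to 148 in control pairs and 32.6 to 183 in ECM pairs. Of the 35 lists with a set test 25 passed, and 20 held with an estimated correlation. 1 other assignment of these 8 libraries to groups gave 1542 calls, so the count alone does not exclude chance. Changes of 2-fold were recovered in 34 of 100 simulated genes, a rate that need not hold for the real fit.

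**Figure D3:**
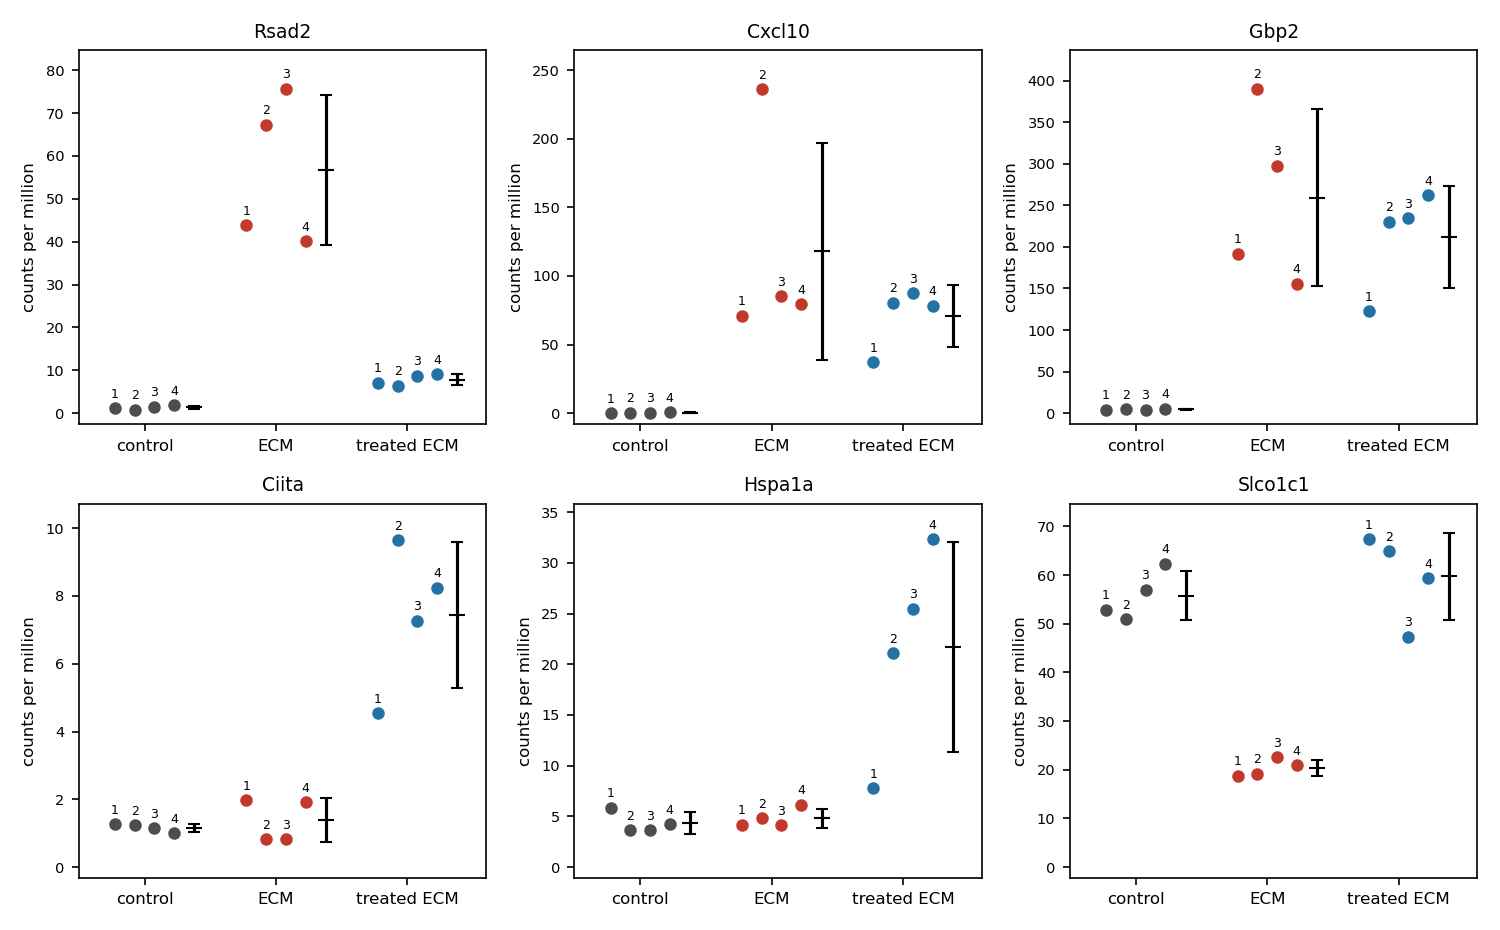
CPM of Rsad2, Cxcl10, Gbp2, Ciita, Hspa1a and Slco1c1 in control, ECM and artesunate-treated ECM. Points are libraries numbered by replicate and the black bar is the mean ± SD over 4.

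Artesunate-treated ECM against ECM asks which of these transcripts differ after 4 days of treatment. Interferon-stimulated, T and NK cell, monocyte, activated microglia, reactive astrocyte and heme-response lists were called lower. Those calls were lost with an estimated correlation (adjusted p = 0.0690 to 0.101). Gpr17, Slco1c1, Drd2 and hemoglobin transcripts rose, as did Ciita and Hspa1a, which were not called in ECM against control.

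Interferon-stimulated genes fell with treatment in 25 of 28 (25 adjusted over the list alone, median -1.66, adjusted p = 1.59e-25, and adjusted p = 0.0690 with an estimated correlation). Rsad2 fell from 56.7 ± 17.4 to 7.85 ± 1.31 CPM (log2 fold change -2.85 ± 0.26, adjusted p = 0.000206), Ifit1 from 125 ± 58.6 to 21.1 ± 6.24 CPM, Mx1 from 12.8 ± 4.43 to 1.37 ± 0.342 CPM, and Isg15 from 38.5 ± 13.7 to 11.5 ± 1.93 CPM. Interferon-gamma-inducible GTPases and regulators fell in 5 of 19 (7 lower and 1 higher adjusted over the list alone, median -0.28, adjusted p = 0.0598). The list passed without ECM 1 (0.0498), ECM 4 (0.0127) or treated 2, 3 or 4 (0.0391, 0.0303 and 0.009999). Irgm1 fell from 69.99 ± 24.4 to 21.5 ± 6.01 CPM (adjusted p = 0.00228), while Gbp2 (adjusted p = 0.545) and Irf1 (adjusted p = 0.706) did not pass. MHC class I genes fell in 7 of 19 (14 adjusted over the list alone, median -0.72, adjusted p = 4.00e-07, and adjusted p = 0.203 with an estimated correlation), with Tap1 falling from 68.8 ± 14.2 to 32.3 ± 6.44 CPM and B2m from 909.6 ± 482 to 262 ± 62.9 CPM. MHC class II genes rose in 2 of 7 (4 adjusted over the list alone, median 0.82, adjusted p = 0.00772, and adjusted p = 0.321 with an estimated correlation). Ciita, the class II transactivator (chromosome 16, 10480059 to 10528418), rose from 1.38 ± 0.649 to 7.43 ± 2.16 CPM (log2 fold change 2.40 ± 0.34, adjusted p = 0.00161).

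Chemokine genes fell in 6 of 15 (7 lower and 2 higher adjusted over the list alone) and rose in 1 (median -0.97, adjusted p = 0.00235, and adjusted p = 0.203 with an estimated correlation). Ccl2 fell from 12.8 ± 4.59 to 1.39 ± 0.653 CPM (adjusted p = 0.00135), Cxcl12 rose to 43.9 ± 11.1 CPM, and neither Cxcl10 (71.0 ± 22.8 CPM, adjusted p = 0.317) nor Cxcl9 (adjusted p = 0.945) passed. Ccl5 fell (log2 -1.89 ± 0.49, adjusted p = 0.0332), a call lost without control 3, ECM 1 or 2 or treated 1 to 3 (adjusted p up to 0.104). Cytokine genes fell in 2 of 13 (7 lower and 1 higher adjusted over the list alone) and rose in 1 (median -0.65, adjusted p = 0.0107, and adjusted p = 0.203 with an estimated correlation). Tnfsf10, the death ligand TRAIL, rose from 12.8 ± 4.43 to 36.4 ± 2.06 CPM (adjusted p = 0.00161), and Ifng did not pass (adjusted p = 0.2005).

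T and NK cell markers fell in 13 of 19 (18 adjusted over the list alone, median -2.07, adjusted p = 3.60e-13, and adjusted p = 0.101 with an estimated correlation). Gzmb fell from 71.5 ± 22.7 to 13.8 ± 6.52 CPM (log2 fold change -2.37 ± 0.34, adjusted p = 0.00161), Gzma from 27.0 ± 14.6 to 7.36 ± 1.77 CPM, and Cd8a from 10.5 ± 2.46 to 2.49 ± 1.48 CPM (adjusted p = 0.0156, lost without treated 1 or 3, at most 0.0550). Monocyte and macrophage markers fell in 10 of 15 (11 adjusted over the list alone, median -1.45, adjusted p = 5.28e-10, and adjusted p = 0.101 with an estimated correlation). Ly6c2 fell from 29.6 ± 14.4 to 5.72 ± 1.14 CPM and Chil3, a chitinase-like protein of alternatively activated macrophages, from 65.3 ± 30.8 to 1.84 ± 0.896 CPM (log2 fold change -5.15 ± 0.43, adjusted p = 0.000175). Neutrophil markers fell in 2 of 6 (2 adjusted over the list alone, median -0.68, adjusted p = 0.00746, and adjusted p = 0.203 with an estimated correlation), with the decoy receptor gene Il1r2 falling from 8.08 ± 2.89 to 0.443 ± 0.419 CPM.

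Innate sensing and NF-kB genes fell in 11 of 21 (14 adjusted over the list alone, median -1.11, adjusted p = 1.36e-07), the only list of this comparison that held with an estimated correlation (adjusted p = 0.0319). Tlr7 fell from 23.5 ± 5.11 to 5.51 ± 2.05 CPM and Tlr13 from 17.7 ± 3.94 to 3.05 ± 0.814 CPM. Inflammasome and cell death genes fell in 1 of 17 (6 adjusted over the list alone, median -0.68, adjusted p = 0.00186, and adjusted p = 0.203 with an estimated correlation). Complement genes fell in 4 of 12 (5 adjusted over the list alone, median -0.95, adjusted p = 6.45e-05, and adjusted p = 0.101 with an estimated correlation), with C4b falling to 51.7 ± 15.3 CPM. Activated microglia genes fell in 10 of 16 (10 lower and 1 higher adjusted over the list alone, median -1.04, adjusted p = 4.00e-07, and adjusted p = 0.101 with an estimated correlation), with Cd86 falling to 2.33 ± 0.249 CPM. Homeostatic microglia genes rose in 2 of 12 (3 adjusted over the list alone, median 0.40, adjusted p = 0.0180, and adjusted p = 0.267 with an estimated correlation), a call lost without ECM 3 (0.0543) or treated 2 (0.0624). Reactive astrocyte genes fell in 10 of 25 (18 adjusted over the list alone, median -1.12, adjusted p = 1.75e-09, and adjusted p = 0.101 with an estimated correlation). Gfap fell from 957 ± 127 to 391.9 ± 129.8 CPM and Serpina3n from 142 ± 29.7 to 23.2 ± 7.75 CPM, while Lcn2 was at 46.1 ± 27.2 CPM (adjusted p = 0.878) and Timp1 did not pass (adjusted p = 0.0635). Homeostatic astrocyte genes fell in 2 of 12 (2 adjusted over the list alone, median -0.21, adjusted p = 0.159).

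Endothelial activation, adhesion and coagulation genes fell in 5 of 19 (9 lower and 1 higher adjusted over the list alone, median -0.43, adjusted p = 0.00609, and adjusted p = 0.246 with an estimated correlation). Procr, the endothelial protein C receptor, fell from 8.45 ± 2.36 to 1.71 ± 0.677 CPM and the plasminogen activator gene Plat from 114 ± 12.3 to 40.6 ± 2.22 CPM, while Icam1 (adjusted p = 0.116), Vcam1 (adjusted p = 0.0722) and Selp (adjusted p = 0.506) did not pass. Endothelial identity genes rose in 1 of 17 (1 higher and 4 lower adjusted over the list alone) and fell in 4 (median -0.03, adjusted p = 0.338). Slco1c1 rose to 59.7 ± 8.91 CPM (log2 fold change 1.55 ± 0.15, adjusted p = 0.000218) and Cdh5 fell to 21.8 ± 2.88 CPM. Pericyte and mural genes fell in 1 of 11 (1 adjusted over the list alone, adjusted p = 0.797). Myelinating oligodendrocyte genes rose in 3 of 15 (3 adjusted over the list alone, median 0.22, adjusted p = 0.119) and precursor genes in 2 of 10 (4 higher and 3 lower adjusted over the list alone, median 0.65, adjusted p = 0.197). Ugt8a rose to 93.9 ± 16.2 CPM and Gpr17 to 59.0 ± 10.01 CPM. Striatum markers rose in 3 of 9 (6 adjusted over the list alone, median 0.76, adjusted p = 2.54e-05, and adjusted p = 0.203 with an estimated correlation), with Drd2 rising to 33.7 ± 4.21 CPM. Choroid plexus markers rose in 1 of 12 (1 adjusted over the list alone, median 1.02, adjusted p = 0.0113, and adjusted p = 0.390 with an estimated correlation), a call lost without treated 4 (0.0960). Neuron markers (0 of 22, adjusted p = 0.508) and cerebellum markers (0 of 11, adjusted p = 0.0677) did not pass. The cerebellum list passed without control 4 (0.0341), ECM 2 (0.00209), ECM 4 (0.0427) or treated 3 (0.0109).

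Heat shock and unfolded protein response genes rose with treatment in 5 of 16 (7 adjusted over the list alone, median 0.53, adjusted p = 0.00105, and adjusted p = 0.185 with an estimated correlation). In ECM against control 0 of 16 had passed (0 adjusted over the list alone, median 0.06, mean -0.04, which differ in sign, adjusted p = 0.658). Hspa1a, an inducible HSP70 (chromosome 17, 34969190 to 34972156), rose from 4.81 ± 0.932 to 21.7 ± 10.4 CPM (log2 fold change 2.16 ± 0.36, adjusted p = 0.00370), and its near-identical copy Hspa1b from 8.23 ± 3.78 to 44.2 ± 25.2 CPM. Arc, a synaptic immediate early gene, rose from 49.6 ± 29.7 to 229.9 ± 74.1 CPM (adjusted p = 0.00763). Immediate early genes rose in 1 of 17 (1 higher and 3 lower adjusted over the list alone) and fell in 2, with the median -0.04 and mean -0.03 opposite in sign to the test (adjusted p = 0.711). Heme, iron and oxidative stress genes fell in 6 of 19 (11 lower and 2 higher adjusted over the list alone, median -0.57, adjusted p = 0.000140, and adjusted p = 0.101 with an estimated correlation), with Hmox1 falling from 68.2 ± 19.9 to 8.92 ± 2.52 CPM (log2 fold change -2.94 ± 0.27, adjusted p = 0.000206) and the transferrin receptor gene Tfrc from 185 ± 30.0 to 95.3 ± 17.9 CPM. Erythroid transcripts rose in 3 of 4 (4 adjusted over the list alone, median 7.33, or 6.44 at the bound, adjusted p = 1.72e-06, and adjusted p = 0.101 with an estimated correlation), and Hbb-bs rose to 29.7 ± 19.8 CPM. Mitochondrially encoded mRNAs fell in 6 of 12 (12 adjusted over the list alone, median -1.32, adjusted p = 1.98e-06, and adjusted p = 0.246 with an estimated correlation), beside the mitochondrial shares of ECM 2 and ECM 3 given above.

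Among the largest falls with treatment, the sulfated steroid carrier gene Slc10a6 fell from 7.72 ± 1.85 to 0.129 ± 0.0967 CPM (adjusted p = 0.000218) and the T-cell checkpoint receptor gene Tigit from 3.66 ± 1.35 to 0.193 ± 0.224 CPM (adjusted p = 0.00161). Klrc1, an NK receptor gene, fell from 2.65 ± 0.296 to 0.160 ± 0.206 CPM (adjusted p = 0.00549) and the cathepsin gene Ctse from 1.28 ± 0.359 to 0.0632 ± 0.0542 CPM (adjusted p = 0.00357). The neutrophil collagenase gene Mmp8 fell from 3.09 ± 1.35 to 0.210 ± 0.214 CPM (adjusted p = 0.00673), Ms4a8a of macrophages from 1.39 ± 0.387 to 0.0960 ± 0.0874 CPM (adjusted p = 0.00330) and the heat shock factor gene Hsf3 from 1.29 ± 0.900 to 0.102 ± 0.0892 CPM (adjusted p = 0.0190, lost without treated 1, 3 or 4, up to 0.0640). Dpep2, a dipeptidase gene with 3 counts over treated libraries, was lower by a ratio of 32.7-fold (counting interval 10.8 to 162, adjusted p = 0.00171). Among the largest rises, Hbb-bt rose at least 65.1-fold (adjusted p = 0.00653) from 0 counts and the parathyroid hormone receptor gene Pth2r from 0.388 ± 0.237 to 2.27 ± 0.418 CPM (adjusted p = 0.00244). Gkn3 rose from 0.142 ± 0.139 to 1.22 ± 0.549 CPM (adjusted p = 0.0105) and Ankk1, beside Drd2 in the genome, from 0.140 ± 0.0996 to 1.34 ± 0.455 CPM (adjusted p = 0.00571). The Wnt receptor gene Fzd10 rose from 0.475 ± 0.366 to 2.87 ± 0.824 CPM (adjusted p = 0.0141) and the lactase gene Lct from 0.771 ± 0.523 to 6.86 ± 5.03 CPM (adjusted p = 0.0154, lost without treated 3, up to 0.0524). Fgf16, a growth factor gene, rose from 0.195 ± 0.125 to 1.202 ± 0.664 CPM (adjusted p = 0.0460, lost without control 1 or 3, ECM 1 to 3 or treated 1 to 4, up to 0.141). The death receptor gene Tnfrsf25 rose from 0.145 ± 0.169 to 2.12 ± 1.58 CPM (adjusted p = 0.0213, lost without ECM 2 or treated 2 or 3, up to 0.0910). The chaperone genes Sdf2l1 and Creld2 of the endoplasmic reticulum rose from 5.80 ± 1.38 to 18.2 ± 5.82 CPM (adjusted p = 0.0110) and from 9.999 ± 1.02 to 21.4 ± 3.34 CPM (adjusted p = 0.00242).

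Between treated ECM and ECM 1225 genes passed, 465 higher and 760 lower, and with a change of at least 2-fold 203 were higher and 479 lower. Of the 35 set tests 24 passed and 1 held with an estimated correlation. The count was 2116 without control 4, 2006 without ECM 4, and 606, 551, 589 and 636 without treated 1 to 4. With the replicate block it was 544 (169 higher and 375 lower). Without both control 4 and ECM 4, an omission chosen after the split result, it was 4004 (1803 higher and 2201 lower). Changes of 2-fold were recovered in 9 of 100 simulated genes, with the spread of controls and few genes changed. That rate need not hold here, where 1225 genes passed and 682 of them changed at least 2-fold. Smaller changes may still be missed.

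Artesunate-treated ECM against control asks what still differs from uninfected brain after treatment. Interferon-stimulated, interferon-gamma-inducible GTPase, MHC, chemokine and endothelial activation lists were called higher than control. T and NK cell and monocyte lists were also called higher. Of reactive astrocyte genes 2 of 25 passed, and the list was called higher, a call lost with an estimated correlation. Over all genes tested, 8 were lower than in control.

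Interferon-stimulated genes were higher than control in 21 of 28 (28 adjusted over the list alone, median 1.86, adjusted p = 9.13e-38, and adjusted p = 0.0103 with an estimated correlation). Rsad2 was 5.79-fold above control (log2 fold change 2.53 ± 0.29, adjusted p = 0.000162). Interferon-gamma-inducible GTPases and regulators were higher in 17 of 19 (19 adjusted over the list alone, median 3.81, adjusted p = 4.96e-55, and adjusted p = 0.0103 with an estimated correlation). Gbp2 was at 212 ± 61.4 CPM (log2 fold change 5.44 ± 0.35, adjusted p = 1.12e-06) and Irf1 at 35.9 ± 7.35 CPM (adjusted p = 1.23e-06). MHC class I genes were higher in 14 of 19 (18 adjusted over the list alone, median 2.17, adjusted p = 2.25e-34), while B2m no longer passed (adjusted p = 0.275). MHC class II genes were higher in 6 of 7 (7 adjusted over the list alone, median 3.38, adjusted p = 1.35e-17), with Cd74 at 92.2 ± 37.2 CPM (adjusted p = 1.49e-05), H2-Aa at 24.1 ± 8.32 CPM, and Ciita 6.34-fold above control (adjusted p = 0.000607).

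Chemokine genes were higher in 9 of 15 (12 adjusted over the list alone, median 3.70, adjusted p = 1.25e-16), with Cxcl10 (log2 7.49 ± 0.66, adjusted p = 1.91e-05) and Cxcl9 (log2 7.89 ± 0.68, adjusted p = 1.69e-05). Cytokine genes were higher in 6 of 13 (8 higher and 1 lower adjusted over the list alone, median 0.92, adjusted p = 2.71e-08), with Il1b at 1.65 ± 0.456 CPM and Tnfsf10 8.51-fold above control. T and NK cell markers were higher in 11 of 19 (15 adjusted over the list alone, median 3.61, or 3.22 at the bound, adjusted p = 9.48e-22), with Gzmb at 13.8 ± 6.52 and Gzma at 7.36 ± 1.77 CPM. Monocyte and macrophage markers were higher in 11 of 15 (12 adjusted over the list alone, median 3.15, adjusted p = 4.43e-22), with Ly6c2 at 5.72 ± 1.14 CPM. Neutrophil markers were higher in 2 of 6 (2 adjusted over the list alone, adjusted p = 0.0102, adjusted p = 0.166 with an estimated correlation, and 0.0619 without treated 4). Endothelial activation, adhesion and coagulation genes were higher in 8 of 19 (11 adjusted over the list alone, median 1.35, adjusted p = 1.36e-12), with Icam1 at 20.9 ± 3.11 CPM, Vcam1 at 83.0 ± 6.69 CPM (adjusted p = 0.00137) and Selp at 5.35 ± 2.31 CPM.

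Innate sensing genes were higher in 6 of 21 (12 adjusted over the list alone, median 0.73, adjusted p = 6.00e-08), inflammasome and cell death genes in 4 of 17 (6 adjusted over the list alone, median 0.83, adjusted p = 9.68e-08), and complement genes in 4 of 12 (8 adjusted over the list alone, median 1.17, adjusted p = 9.63e-08). Activated microglia genes were higher in 3 of 16 (5 adjusted over the list alone, median 0.66, adjusted p = 1.96e-05, and adjusted p = 0.110 with an estimated correlation) and reactive astrocyte genes in 2 of 25 (8 adjusted over the list alone, median 0.79, adjusted p = 3.65e-07, and adjusted p = 0.110 with an estimated correlation). Lcn2 was at 117 times control, while Gfap (adjusted p = 0.139) and Serpina3n (adjusted p = 0.507) no longer passed. Heat shock and unfolded protein response genes were higher in 4 of 16 (6 adjusted over the list alone, median 0.29, adjusted p = 0.000503, and adjusted p = 0.110 with an estimated correlation), with Hspa1a at 21.7 ± 10.4 CPM (adjusted p = 0.00254). Immediate early genes were higher in 6 of 17 (14 adjusted over the list alone, median 1.54, adjusted p = 9.83e-14, and adjusted p = 0.0669 with an estimated correlation). Fos passed (adjusted p = 0.0442) and was lost without control 1, 2 or 4, ECM 1 or 2 or treated 2 to 4 (up to 0.140), and Arc passed (adjusted p = 0.0155) and was lost without control 1 or 2 or treated 3 (up to 0.0686). Heme, iron and oxidative stress genes were higher in 3 of 19 (4 higher and 1 lower adjusted over the list alone) and lower in 1 (median 0.37, adjusted p = 0.00300, and adjusted p = 0.144 with an estimated correlation). Hmox1 passed (adjusted p = 0.0462) and was lost without control 1 to 4, ECM 3 or 4 or treated 2 to 4 (up to 0.176).

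The largest differences left after treatment were in genes with few control counts. With 0 control counts, Serpina3f was at least 904-fold (adjusted p = 1.05e-05) above control, Ubd at least 218-fold (adjusted p = 0.000257) and Cd8b1 at least 39.2-fold (adjusted p = 0.0128). Also from 0, Clec4e was at least 30.2-fold (adjusted p = 0.00760), Il1rn at least 30.5-fold (adjusted p = 0.000917) and Gimap3 at least 28.0-fold (adjusted p = 0.00361). The T-cell attractant gene Cxcl11 was 335-fold (counting interval 59.6 to 13250.4, adjusted p = 4.86e-05) above control. Genes called in all 3 comparisons also included the T-cell gene Ms4a4b, which went from 0.0380 ± 0.0761 in control to 16.6 ± 9.53 in ECM and 2.46 ± 1.43 CPM with treatment, and its relative Ms4a4c (0.0138 ± 0.0277, 7.75 ± 2.25 and 2.24 ± 1.11 CPM). The coagulation factor gene F10 was 129-fold (counting interval 22.8 to 5140.0, adjusted p = 0.000194) above control and the myeloid gene Plac8 rose from 0.127 ± 0.0626 to 8.88 ± 3.71 CPM (adjusted p = 4.89e-05). Between treated ECM and ECM the adjusted p was 0.00506 for Ms4a4b. It was 0.0148 for Ms4a4c, lost without treated 4, up to 0.0549. For F10 it was 0.0251, lost without ECM 3 or treated 2 or 4, up to 0.0789. For Plac8 it was 0.0401, lost without control 1 to 3, ECM 2 or treated 1 to 4, up to 0.103. Few genes were lower than control. The matrix gene Hmcn1 fell from 8.03 ± 1.42 to 3.38 ± 0.770 CPM (adjusted p = 0.01001, lost without treated 2, up to 0.0508). The monooxygenase gene Fmo2 fell from 6.67 ± 1.65 to 1.97 ± 0.763 CPM (adjusted p = 0.00973). Ptprb, an endothelial phosphatase gene, fell from 70.4 ± 12.7 to 32.8 ± 9.25 CPM (adjusted p = 0.0117, lost without treated 4, up to 0.0575). The kinase gene Bmx fell from 2.77 ± 0.609 to 1.01 ± 0.167 CPM (adjusted p = 0.0264, lost without control 1, 3 or 4 or treated 1 to 4, up to 0.110). Asb14 fell from 1.15 ± 0.590 to 0.241 ± 0.0717 CPM (adjusted p = 0.0325, lost without control 2 to 4, ECM 1 or treated 1 to 4, up to 0.123). Bach2, a transcription factor gene, fell from 13.5 ± 1.49 to 8.38 ± 0.744 CPM (adjusted p = 0.0467, lost without control 1 to 4, ECM 1 or 4 or treated 1 to 4, up to 0.188). Tfrc fell from 165 ± 10.8 to 95.3 ± 17.9 CPM (adjusted p = 0.0176, lost without control 1 or 3 or treated 2 to 4, up to 0.0907).

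Several lists had 0 called genes in treated ECM against control. These were homeostatic microglia (adjusted p = 0.745), homeostatic astrocyte (0.568), endothelial identity (0.816), pericyte and mural (0.129), striatum (0.698), choroid plexus (0.193) and erythroid transcripts (0.404). The choroid plexus list passed without control 2 (0.0158) or treated 4 (0.00458), and the erythroid list without treated 4 (0.0339). Myelinating oligodendrocyte (0.856), precursor (0.856), neuron (0.849) and cerebellum lists (0.896) also had 0 called genes, and their medians, means and tests differed in sign. Mitochondrially encoded mRNAs had 0 called genes and a list call toward lower (median -0.52, adjusted p = 0.00268, and adjusted p = 0.502 with an estimated correlation). Of 14624 genes 297 passed, 289 higher and 8 lower, and with a change of at least 2-fold 279 were higher and 6 lower. Of 35 set tests 22 passed and 12 held with an estimated correlation. Changes of 2-fold were recovered in 23 of 100 simulated genes, a rate that need not hold for the real fit. Absence from these calls is weak evidence of a return to control.

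Of the 986 genes changed at least 2-fold in ECM, treated libraries kept a median share of 0.424 of the change (0.422 with 19 genes that had a group at 0 placed at their bound). The share was 0.480 for the 829 higher genes and 0.102 for the 157 lower genes. Per treated library the median share was 0.271, 0.442, 0.472 and 0.498. The genes were chosen on the same ECM and control libraries that enter the share, which biases it. In 36 splits that chose the genes on some ECM and control libraries and measured them on others, the median share was 0.491 (0.382 to 0.698). The shares by direction and by list had no such check. By list, the share was 0.490 for interferon-stimulated genes (28 genes), 0.944 for interferon-gamma-inducible GTPases (17), 0.777 for MHC class I (19) and 1.23 for MHC class II (5). It was 0.641 for T and NK cell markers (18), 0.363 for reactive astrocyte (18) and 0.285 for glucocorticoid-response genes (9). Of the 986, 544 (55.2%) were called with treatment in the direction opposite to ECM, and 123 of these still differed from control. In all 269 (27.3%) still differed from control, and 296 were neither. Across comparisons 273 genes were higher in both ECM and treated ECM than in control, where independence gives 20.6. With separate control libraries, 2 per comparison, 655 and 142.5 genes were higher and 135 were shared (independence 6.44, medians of 6 splits). Genes higher in ECM and lower with treatment numbered 519 (independence 54.0), and the reverse 242 (14.7). With separate ECM libraries these were 277.5 of 864.5 and 496.5 (27.9), and 67 of 274 and 236.5 (3.39).

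The authors' deposited tables, limited by their titles to an unadjusted p of 0.05 and a log2 fold change of 1, list 1459 genes for ECM against control, 1361 for treated ECM against ECM and 637 for treated ECM against control. Of these genes in the authors' deposited tables, 1234, 1131 and 564 were tested here. At an adjusted p below 0.05, 986, 675 and 284 passed in the same direction, and 0 in the opposite direction.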

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

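Chosen after the results were seen were the exchange fits of control 4 and ECM 4 and the test of the cerebellum score over control libraries. In 227 groups of 4 values, 18 had 1 library outside the range of the other 3 by a gap large against the whole range, where chance gives about 1 in 20, or 11.35. ECM 4 had the largest total count (18886822 against at most 13999627 in its group), and control 4 the largest share among controls of reads in its 10 most abundant genes (12.6%), a share raised by mitochondrial reads. List scores apart from their group were MHC class I in control 4 (2.34), B cell in treated 2 (0.57), complement and endothelial activation in treated 1 (2.89 and 2.89), reactive astrocyte in ECM 2 (5.09), myelinating oligodendrocyte in treated 4 (7.48) and cerebellum in control 4 (1.02). CPM values apart from their group were Cxcl10 in ECM 2 (236) and treated 1 (37.3), Gbp2 in treated 1 (123), Prf1 in control 3 (0.152), Icam1 in control 4 (1.36), Irf1 in control 2 (2.92), P2ry12 in control 4 (101), and Mbp in treated 4 (6309.9). Treated 1 also kept the smallest share of the ECM change (0.271), which goes with its low Cxcl10, Gbp2, complement and endothelial scores. Prf1 in control 3 rests on 2 counts. Of the 18 groups, 1 belongs to a gene not reported here. No library was left out of the results for these values.

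Over all 35 ways to split the 8 control and ECM libraries, 2 gave at least 1501 calls, so chance is not excluded by this count. The other, an exchange of control 4 and ECM 4, gave 1542 calls, of which 85 matched the real calls in direction, and 402 had a change of at least 2-fold against 986. Immune scores place control 4 with controls and ECM 4 with ECM, so a structure of the samples other than infection may add to both counts. The exchanged grouping also parted the libraries by mitochondrial reads. These were 11.1, 8.22, 15.8 and 13.7% in control 4 and ECM 1 to 3, against 5.93, 6.03, 6.95 and 5.78% in control 1 to 3 and ECM 4. Whether this share marks that structure was not tested. With the cerebellum score in the model the counts were 2870 as labelled and 2610 exchanged. For treated ECM against ECM and treated ECM against control, 1 of 35 splits reached the real count (1225 and 297) and the highest other count was 0. This met the bound written before for rejecting chance, to the extent 35 splits allow. Splits that mix the groups also raise the fitted spread, so a count of 0 in them is weak evidence.

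Cerebellar transcripts differed many-fold between libraries of 1 group, by 5.32, 5.81 and 2.78 (log2) in controls, ECM and treated ECM. Other cerebellar genes, outside the list, differed by a median of 2.51 between the highest and lowest library, which is consistent with pieces of brain that held different amounts of cerebellum. A correction for GC content kept 97.0% of the range, which speaks against GC bias. The range of 5.32 over uninfected controls rests on control 4 (0.629 without it). Infection or treatment cannot account for the low score of that library. As a source of the ranges in ECM and treated ECM they stay open. Striatal, choroid plexus and oligodendrocyte changes could in part follow the piece of brain taken, which no label records.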

How the results depend on the processing

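The alternatives with the GC correction, the cerebellum score, displaced genes, 3 libraries left out, and control 4 and ECM 4 left out were chosen after the files were seen, the last after the split result was seen. The ECM against control count of 1501 was 2016 with DESeq2, 1486 with limma-voom, 866 from the 8 libraries of the 2 groups alone (82.9% higher against 69.3%), 999 with the replicate block and 2158 with GC correction. It was 2870 with the cerebellum score (56.7% higher), 2722 without control 4, ECM 2 and ECM 3 (57.2% higher) and 2477 without control 4 and ECM 4. The treated ECM against ECM count of 1225 was 2147 with DESeq2, 1277 with limma-voom, 544 with the replicate block, 2027 with GC correction, 1846 with the cerebellum score, 2287 without the 3 libraries and 4004 without control 4 and ECM 4. The treated ECM against control count of 297 was 463 with DESeq2, 251 with limma-voom, 219 with the replicate block, 474 without the 3 libraries and 279 without control 4 and ECM 4. From the 8 libraries of the 2 groups alone, treated ECM against ECM gave 1059 and treated ECM against control 313. Controls have no weight in treated ECM against ECM and act on its count only through the shared spread, scaling and gene filter. Which of these acted, and the cause of each other change in count, was not tested.

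Counts with at least a 2-fold change were 986, 682 and 285 in the 3 comparisons. At an adjusted p below 0.01 they were 818, 351 and 191, and at an unadjusted p below 0.05 with a 2-fold change 1238, 1096 and 557. Set tests that passed fell from 25, 24 and 22 to 20, 1 and 12 with an estimated correlation. Genes of the authors' deposited tables with an unadjusted p below 0.05 and a 2-fold change here in the same direction numbered 1217, 1068 and 535, against 986, 675 and 284 called.

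Leaving out 1 library gave 1061 to 1701 calls in ECM against control, 551 to 2116 in treated ECM against ECM, 226 to 327 in treated ECM against control, and a residual share of 0.388 to 0.481 (0.424 with all). The share was 0.293 without control 4 and ECM 4, chosen after the split result; the cause was not tested. Over 17577 results of named genes in the alternatives, 16612 were the same, 745 weaker, 220 stronger and 0 reversed, and 489 of 654 gene and comparison pairs kept direction and call in every alternative.

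Libraries with the same replicate number deviated together in 3 of 12 pairs (correlations -0.61 to 0.30, over 0.1 in those 3), and 1 of 12 libraries correlated best with its own number, so the numbers were not taken as pairs. With the replicate block the cholesterol synthesis list was no longer called in treated ECM against ECM (adjusted p = 0.0540) and the cerebellum list was (adjusted p = 0.0462); the block changed no other list call.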

Other observations

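Glucocorticoid-response genes rose in ECM in 9 of 12 (11 adjusted over the list alone, median 1.26, adjusted p = 1.02e-10) and fell with treatment in 7 of 12 (9 adjusted over the list alone, median -0.97, adjusted p = 4.00e-07, and adjusted p = 0.101 with an estimated correlation). Cdkn1a, a cell cycle inhibitor, rose from 16.2 ± 2.54 to 126 ± 34.0 CPM and fell to 29.0 ± 4.23 CPM. In treated ECM against control 0 of 12 (2 adjusted over the list alone) passed, with a list call (adjusted p = 0.00167, and adjusted p = 0.166 with an estimated correlation). Hypoxia and glycolysis genes were higher in ECM in 4 of 15 (5 higher and 1 lower adjusted over the list alone, median 0.41, adjusted p = 0.00210), fell with treatment in 4 of 15 (4 lower and 1 higher adjusted over the list alone, adjusted p = 0.149) and were above control in 2 of 15 (2 adjusted over the list alone, adjusted p = 0.0207, and adjusted p = 0.0669 with an estimated correlation). Pfkfb3, a glycolytic regulator, rose from 46.2 ± 1.91 to 101 ± 31.7 CPM and was at 103 ± 13.8 CPM, while Angptl4, a lipase inhibitor, rose from 4.55 ± 0.278 to 19.4 ± 3.25 CPM and fell to 6.76 ± 2.82 CPM.

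Proliferation genes were higher in ECM in 7 of 14 (10 adjusted over the list alone, median 1.27, adjusted p = 2.92e-07), fell with treatment in 3 of 14 (5 adjusted over the list alone, adjusted p = 0.000564, and adjusted p = 0.101 with an estimated correlation), and had 0 called genes against control after treatment (list adjusted p = 0.00846, adjusted p = 0.155 with an estimated correlation, and 0.0531 without control 2). The cyclin gene Ccnb2 rose from 0.672 ± 0.223 to 2.88 ± 0.846 CPM, and Mki67 of cycling cells from 2.80 ± 1.61 to 15.5 ± 6.91 CPM. Cholesterol synthesis genes were higher in ECM in 2 of 15 (2 adjusted over the list alone, adjusted p = 0.396), with 0 lower after treatment and a list call (adjusted p = 0.0466, and adjusted p = 0.468 with an estimated correlation) that was lost without control 2 (0.0528), ECM 1 (0.178), ECM 3 (0.201) or treated 1 (0.162). Against control after treatment 0 passed (adjusted p = 0.156). Of the hypothalamus and pituitary markers 1 of 10 (1 adjusted over the list alone) was higher in ECM (adjusted p = 0.450), the feeding peptide gene Agrp, which rose from 0.830 ± 0.333 to 4.26 ± 2.01 CPM. In the other comparisons 0 passed (adjusted p = 0.952 and 0.434).

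Chosen after the results were seen were the sum over hemoglobin genes and the permutation test between the 2 interferon lists. Summed hemoglobin CPM was 29.0 ± 14.3 in controls, 0.246 ± 0.193 in ECM and 46.9 ± 32.5 in treated ECM. The sum was 118-fold lower in ECM, which speaks against reads moved between near-identical genes, and the median log2 change after GC correction was -7.19, which speaks against GC bias. For less blood left in ECM tissue, platelet transcripts had a median log2 change of 0.390 over 3 genes, with 29, 116 and 36 control counts. This met the bound written before for rejecting that cause, and that label stands. Outside the test, control and ECM counts were 2 and 19 for Ppbp, 0 and 8 for Tubb1 and Clec1b, and 13 and 16 for Gp9. They were 0 and 1 for Gp6, and 0 and 0 for Gp1bb and Treml1. Platelets held in vessels of ECM brains could offset less blood, so the test by itself cannot exclude that cause. After the value was seen the label was for a time changed to undecided, because 6 of 10 platelet genes had 2 counts or fewer over the controls. That change was withdrawn, since those genes were not in the test. Platelets held in vessels of ECM brains and fewer young red cells in blood were not tested and stay open.

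Interferon-gamma-inducible GTPases kept more of their ECM change after artesunate than interferon-stimulated genes, by 0.454 in median share. Both shares rest on genes chosen on the same ECM and control libraries, without a check on other libraries. The difference was 0.487 without control 4, ECM 2 and ECM 3, 0.467 with GC correction and 0.353 between 16 pairs of genes matched on their ECM change, which speaks against libraries that stand apart, GC bias and the size of the change. Per library, the score difference between the lists moved by -1.43 from ECM to treated ECM (exact permutation p = 0.0286, the smallest possible of 70 relabellings). That test used the libraries and lists in which the pattern was seen, so it restates the pattern and does not bear on its source. Treatment, which the design names, stays open and was not tested apart from these values.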
